A study of Auxenochlorella pyrenoidosa with 12 samples.

How the data were processed

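Libraries were made from total RNA of whole algal cells with the Illumina TruSeq RNA chemistry, per the labels' protocols. The deposited table holds FPKM, fragments scaled to contig length and library total, for 29140 contigs in 12 libraries, and the unit is known from the name of the deposited table. Contig names follow the pattern of the Trinity assembler and end in a further number from 1 to 4, whose meaning is not given in the sources used here. Without that number 22000 distinct names remain. The version of the assembler, the aligner, the estimator of abundance and any filter are not given in the sources used here. The values are estimates and not counts divided by length, since the smallest positive value is 2.26e-146. The total depth of each library is unknown, so no counting interval or floor is given. Summed FPKM lay between 503295 and 561291 per library, and between 14015 and 18475 contigs reached 1 FPKM.

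Samples were grouped by the dose in their titles, 3 libraries to a group. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend in the prior variance, for 16732 contigs with a mean of at least 1 FPKM over the 12 libraries. A fold change is on the log2(FPKM + 1) scale, which understates the change of low contigs. All 4 groups shared 1 fit with 8 residual degrees of freedom, and contigs with a Benjamini-Hochberg adjusted p under 0.05 in limma's two-sided moderated test were called. Tests covered each dose against control, each pair of doses, any difference among the groups and a linear trend with the dose in mg/L. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

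Groups, tests, alternatives and the rule for named contigs were set before the data were examined. The rule took called contigs with a mean of at least 5 FPKM in the higher group and no overlap between dose and control values. Without gene names it allows, for each dose against control, the 2 contigs with the largest rise and the 2 with the largest fall. The share of contigs without overlap was 34.1% at 0.5 EC50, 29.7% at 0.2 EC50 and 28.6% at 0.1 EC50 against control, where chance gives 10%. Between 0.2 and 0.1 EC50, where 0 contigs were called, it was 18%, so a share over 10% also came without any call. Gene lists had also been set, and could not be matched to contigs without names, so no list was tested.

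Alternatives covered a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, median-of-ratios scaling, an equal total in every library, quantile normalization, no prior trend, library weights, a minimum change of 2-fold, the replicate number as a block, fits of the 2 groups compared only, and leaving out each library. Another 3 were added after seeing the data: leaving out the libraries whose low values step differently, a batch term for those steps, and the calls shared by 3 scalings. The steps were found from ratios of values between 0.01 and 1 FPKM in pairs of libraries, and libraries were clustered into 3 sets of 8, 3 and 1, a number chosen after seeing the data. The set of 3 (0.2 EC50 replicate 2, 0.1 EC50 replicates 2 and 3) holds no control, so no comparison with control can be made within it. The set of 1 is control replicate 2, which the batch term fits exactly. With that term, comparisons with control therefore rest on control replicates 1 and 3 only.

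The procedure was tested on simulated values for 0.5 EC50 against control over 16732 contigs. Of these, 200 were changed, all with a mean of at least 5 FPKM. Noise was drawn independently for each contig and library, without shifts of whole libraries. The procedure recovered 26.9% of contigs changed by 1.5-fold, 67.2% of those changed by 2-fold and 89.4% of those changed by 4-fold, with 5 false calls among 127. Recovery of contigs under 5 FPKM, and false calls where whole libraries shift, were not tested.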

Results

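Transcript levels were measured in whole cells of Auxenochlorella pyrenoidosa, a unicellular green alga also known as Chlorella pyrenoidosa. Cultures were exposed to potassium peroxymonosulfate, an oxidant used in water treatment. The series asks how exposure over 12 days affects the alga at fractions of its EC50, the concentration with a median effect. There were 3 libraries each of an unexposed control and of 0.1, 0.2 and 0.5 EC50, which correspond to 1.70, 3.40 and 8.49 mg/L. The day on which RNA was taken for these 12 libraries is not given in the sources used here. The deposited table gave FPKM values for 29140 Trinity contigs, assembled transcript sequences, of which 16732 had a mean of at least 1 FPKM and were tested. It does not pair contig identifiers with gene names, so contigs are given by identifier only. Nothing says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

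The 3 contigs with the highest mean level held between 14.1% and 17.6% of the summed FPKM of a library. The first of them had 43301 ± 2304 FPKM in the controls and 44361 ± 3591 at 0.5 EC50 (SD, n = 3). None of these 3 contigs differed from control at any dose in limma's moderated test (adjusted p from 0.2 to 0.872). The number of contigs at 1 FPKM or more was 16983 ± 1130 in the controls, 15735 ± 996 at 0.1 EC50, 16247 ± 1935 at 0.2 EC50 and 18350 ± 170 at 0.5 EC50 (SD, n = 3). Pairs of libraries within a group had correlations of 0.899 to 0.961 across contigs, which are not independent replicates. The 0.5 EC50 libraries, 0.2 EC50 replicate 3, 0.1 EC50 replicates 2 and 3 and control replicate 2 correlated best within their own group. Each other library correlated best with another group, up to 0.9694 between replicate 1 of 0.2 and of 0.1 EC50. Only control replicate 3 had a lower mean correlation with its own group (0.9189) than with the other groups (0.924). In 8 libraries the ratios of low values between libraries clustered at shared steps. These steps put their depth relative to control replicate 1 at 1 to 1.14. Only log2 ratios within 0.5 of equal values were searched, so a larger difference in depth could not be found. The step against control replicate 1 held 8.93% to 16.1% of low-value contigs in the rest of this set. In the other 4 libraries it held 3.99% to 6.43%. Control replicate 2, 0.2 EC50 replicate 2 and 0.1 EC50 replicates 2 and 3 did not share those steps, and each comparison is therefore also given without these 4 libraries.

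At 0.5 EC50 the contig TRINITY_DN13892_c0_g1_i1_2 rose from 7.80 ± 2.69 FPKM in the controls to 278 ± 54.8 FPKM (SD, n = 3). The difference was 5.02 ± 0.381 on the log2 scale (SE, adjusted p = 7.05e-05). Its means were 18.5 FPKM at 0.1 EC50, where it was not called (adjusted p = 0.0837), and 48.8 FPKM at 0.2 EC50, where it was called (log2 difference 2.42, adjusted p = 0.00359). TRINITY_DN18466_c0_g1_i1_3 rose from 1.39 ± 0.339 to 61.0 ± 6.52 FPKM (log2 difference 4.70 ± 0.265, adjusted p = 1.04e-05). It stood at 2.84 FPKM at 0.1 EC50 (adjusted p = 0.15) and at 9.29 FPKM at 0.2 EC50 (adjusted p = 0.00141). TRINITY_DN1868_c0_g1_i1_1 fell from 15.6 ± 4.73 to 2.19 ± 0.0638 FPKM (log2 difference -2.34 ± 0.355, adjusted p = 0.00481) and was also called lower at 0.2 and 0.1 EC50. TRINITY_DN2512_c0_g2_i1_3 fell from 10.3 ± 1.41 to 1.36 ± 0.316 FPKM (log2 difference -2.27 ± 0.242, adjusted p = 0.000622). That contig was also called at 0.2 EC50 (adjusted p = 0.0178) and was not called at 0.1 EC50 (adjusted p = 0.139).

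Across all tested contigs, 1596 differed between 0.5 EC50 and control, 1186 higher and 410 lower. Of these, 315 were at least 2-fold higher and 140 at least 2-fold lower. Among the 315 contigs, 90 were also called higher at 0.2 EC50 and 30 at 0.1 EC50, and in direct comparisons 128 were higher than at 0.2 EC50 and 208 higher than at 0.1 EC50. Among the 140 contigs, 75 were also called lower at 0.2 EC50 and 58 at 0.1 EC50, and 13 were lower than at 0.2 EC50 and 45 lower than at 0.1 EC50. Both sets were picked with the 0.5 EC50 and control libraries that entered these comparisons again, which raises the counts. Over all 16732 tested contigs, 930 were higher and 208 lower at 0.5 than at 0.2 EC50. Against 0.1 EC50, 2808 were higher and 411 lower at 0.5 EC50. The split between higher and lower calls at 0.5 EC50 against control turned under 2 of 3 other scalings. An equal total in every library kept it at 715 higher and 412 lower. Median-of-ratios scaling gave 468 higher and 705 lower and quantile normalization gave 581 and 889, against a median log2 difference of all contigs of 0.16 as deposited and 0.03 after median-of-ratios scaling. Under deposited values and both of these scalings, 404 contigs were called higher and 406 lower. The total was 624 without the 4 libraries with other low-value steps and 750 with those steps as a batch term, and without 0.5 EC50 replicate 2 or 3 or control replicate 1, 2 or 3 it was 439, 748, 883, 612 and 753.

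**Figure D1:**
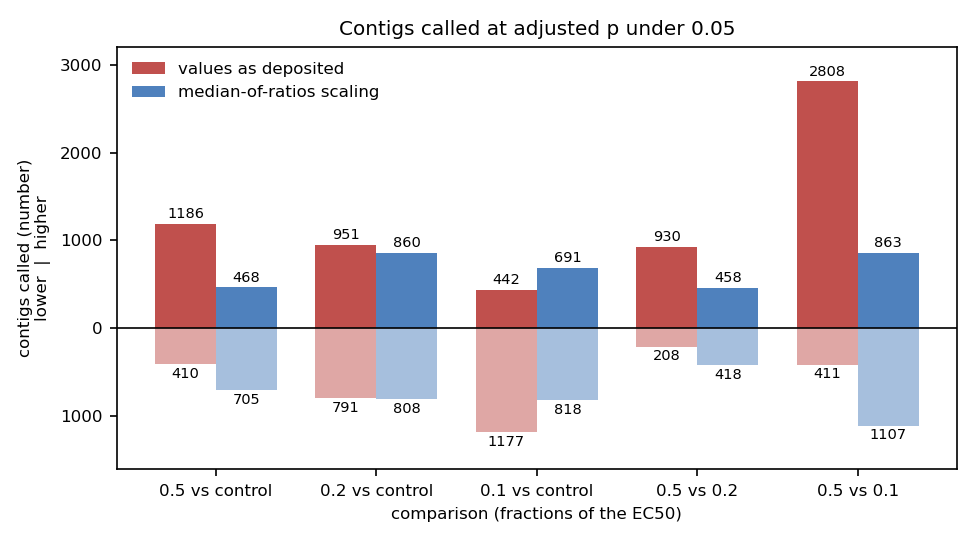
Number of contigs called at an adjusted p under 0.05 (limma), for FPKM as deposited (red) and after median-of-ratios scaling (blue). Higher calls stand above 0 and lower calls below 0 (paler). The comparison of 0.2 with 0.1 EC50, with 0 calls under both, is not drawn. For 0.5 EC50 against control, 1186 contigs were higher and 410 lower as deposited, and 468 and 705 after scaling.

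At 0.2 EC50 the contig with the largest rise under the fixed rule, TRINITY_DN6226_c0_g4_i1_3, was listed at 0, 0 and 3.823 FPKM in the controls and at 21.82, 7.462 and 28.56 FPKM in the exposed libraries. Its log2 difference was 3.40 ± 0.742 (SE, adjusted p = 0.0159), and it was also called higher at 0.5 EC50 (adjusted p = 0.0201) and 0.1 EC50 (adjusted p = 0.0468). At 0.1 EC50 it was listed at 26.14, 3.669 and 8.89 FPKM, which overlap the control values. Its call at 0.2 EC50 ended without 0.2 EC50 replicate 1 (log2 difference 3.23) or 3 (3.04). It also ended without control replicate 1 or 2 (3.025 each) and without the 4 libraries with other low-value steps (3.56). TRINITY_DN16465_c0_g1_i1_4 rose from 0.164 ± 0.0525 to 6.90 ± 1.56 FPKM (SD, n = 3; log2 difference 2.74 ± 0.546, adjusted p = 0.0108). It was called at 0.5 EC50 (adjusted p = 0.0219) and not at 0.1 EC50 (adjusted p = 0.316), and its call at 0.2 EC50 ended without the 4 libraries with other low-value steps (log2 difference 2.62) and with those steps as a batch term (2.74). TRINITY_DN11245_c0_g1_i1_1 fell from 12.9 ± 5.42 to 0.560 ± 0.138 FPKM (log2 difference -3.09 ± 0.288, adjusted p = 0.000466). TRINITY_DN2075_c0_g1_i8_3 fell from 30.5 ± 3.29 to 2.78 ± 0.719 FPKM (log2 difference -3.07 ± 0.153, adjusted p = 1.44e-05). Both contigs that fell were called lower at the other doses too, with log2 differences of -2.04 and -2.09 at 0.5 EC50 and -3.13 and -2.39 at 0.1 EC50.

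In total 1742 contigs differed between 0.2 EC50 and control, 951 higher and 791 lower, and 143 and 247 of these by at least 2-fold. The split differed by the last number of the contig name, whose meaning is not known here. Names ending in 1, 2, 3 and 4 gave 178, 207, 129 and 437 higher and 188, 84, 354 and 165 lower. After median-of-ratios scaling they gave 157, 194, 110 and 399 higher and 190, 79, 381 and 158 lower. The cause was not tested. Over all tested contigs, median-of-ratios scaling gave 860 higher and 808 lower. The total was 488 without the 4 libraries with other low-value steps and, without 0.2 EC50 replicate 1 or 2 or control replicate 1 or 3, it was 928, 1102, 1138 and 923.

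At 0.1 EC50, TRINITY_DN11245_c0_g1_i1_1 again showed the largest fall under the rule, to 0.529 ± 0.255 FPKM from 12.9 ± 5.42 FPKM (SD, n = 3; log2 difference -3.13 ± 0.288, adjusted p = 0.00032). TRINITY_DN3211_c0_g1_i2_3 fell from 14.8 ± 2.59 to 1.54 ± 0.204 FPKM (log2 difference -2.63 ± 0.197, adjusted p = 0.000258). At 0.5 EC50 the latter contig stood at 7.90 ± 2.11 FPKM, lower than control (log2 difference -0.85, adjusted p = 0.0257) and higher than at 0.1 EC50 (log2 difference 1.78, adjusted p = 0.000497). TRINITY_DN12187_c0_g1_i1_1 was listed at 0.6401, 0 and 0 FPKM in the controls and at 2.467, 10.46 and 4.919 FPKM at 0.1 EC50 (log2 difference 2.39 ± 0.549, adjusted p = 0.0212). It was not called at 0.2 EC50 (adjusted p = 0.804) or 0.5 EC50 (adjusted p = 0.909). Its call at 0.1 EC50 ended without 0.1 EC50 replicate 2 (log2 difference 1.94) or 3 (2.42) and without control replicate 2 or 3 (2.27 each). It also ended without the 4 libraries with other low-value steps (1.44), with the batch term (2.12) and with a pseudocount of 0.1 (4.72). TRINITY_DN1915_c0_g4_i1_2 rose from 1.36 ± 0.531 to 8.52 ± 1.92 FPKM (log2 difference 2.02 ± 0.561, adjusted p = 0.0469) and was not called at 0.2 or 0.5 EC50 (adjusted p = 0.0737 and 0.231). Its levels there were 6.89 ± 0.920 and 5.48 ± 4.46 FPKM, and neither differed from 0.1 EC50 in limma's test (adjusted p = 0.876 and 0.259). The rise is therefore not shown to be particular to 0.1 EC50. Its call at 0.1 EC50 ended when any library other than 0.5 EC50 replicates 1 and 3 was left out, with log2 differences between 1.84 and 2.17. It also ended without the 4 libraries with other low-value steps (2.47), with the batch term (2.23), with a pseudocount of 0.1 (2.615), without a filter and without the prior trend (2.02 each).

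**Figure D2:**
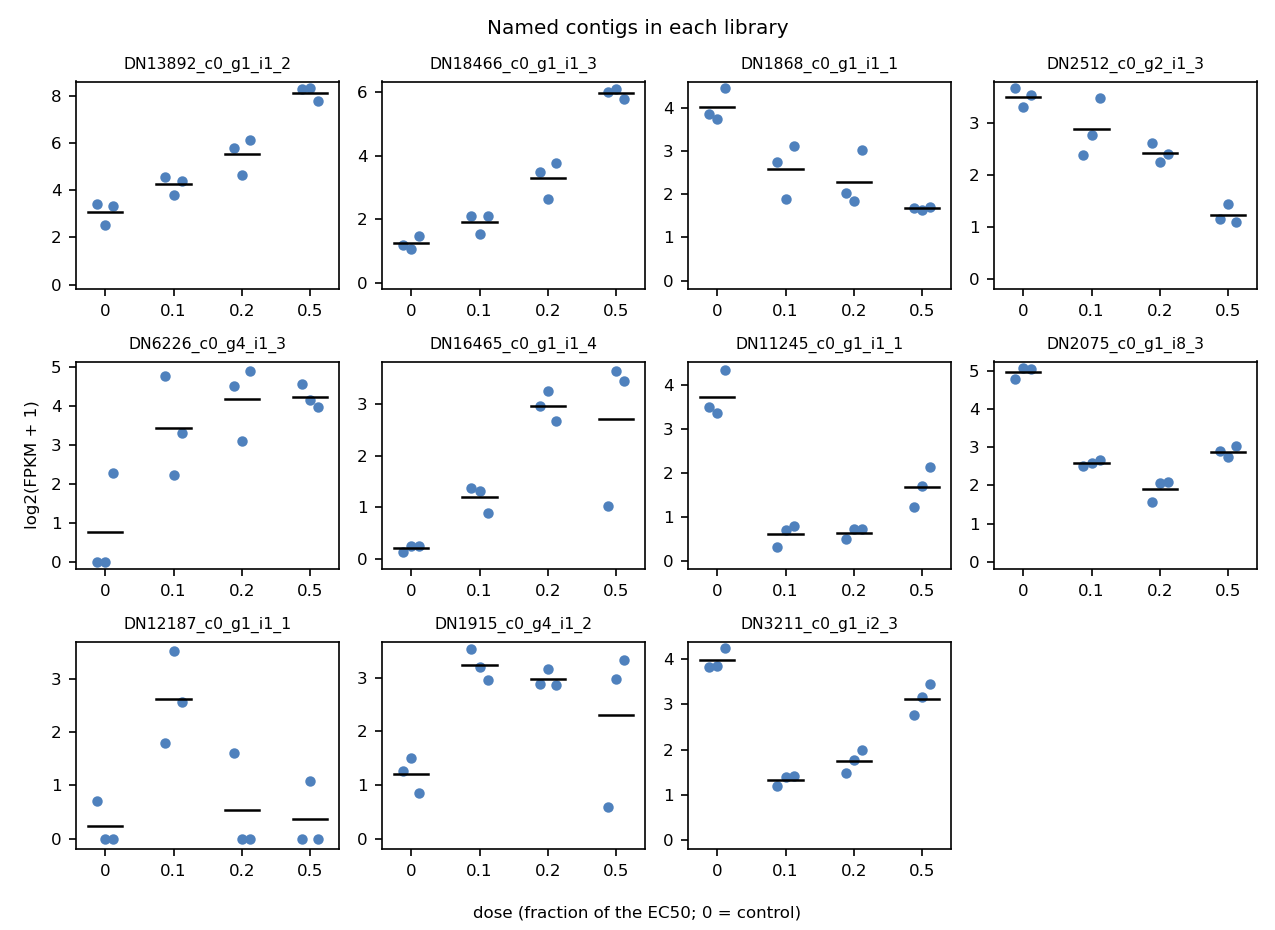
Level of each named contig as log2(FPKM + 1) in each library (points) and the mean of the 3 libraries of a group (lines), by dose as a fraction of the EC50, with 0 for control. Identifiers are shown without their common prefix. TRINITY_DN13892_c0_g1_i1_2 had means of 7.80, 18.5, 48.8 and 278 FPKM from control to 0.5 EC50.

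In total 1619 contigs differed between 0.1 EC50 and control, 442 higher and 1177 lower, and 59 and 319 of these by at least 2-fold. Here too the split differed by the last number of the contig name, and the cause was not tested. Names ending in 1, 2, 3 and 4 gave 84, 110, 71 and 177 higher and 268, 120, 494 and 295 lower. After median-of-ratios scaling they gave 133, 179, 106 and 273 higher and 180, 59, 386 and 193 lower. Over all tested contigs, an equal total gave 358 higher and 1095 lower and quantile normalization 544 and 844. Median-of-ratios scaling gave 691 higher and 818 lower, which moved the share of higher calls from 27.3% to 45.8%. The total was 152 without the 4 libraries with other low-value steps, which left 1 library at 0.1 EC50 that was assumed to vary like the other groups, and 510 with those steps as a batch term. Without 0.1 EC50 replicate 2 or control replicate 1 or 3 it was 812, 1014 and 837.

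The doses were also compared with each other. TRINITY_DN13892_c0_g1_i1_2 was higher at 0.5 than at 0.2 EC50 by 2.60 ± 0.381 on the log2 scale (SE, adjusted p = 0.00418), and TRINITY_DN18466_c0_g1_i1_3 by 2.66 ± 0.265 (adjusted p = 0.000915). Between 0.5 and 0.2 EC50, 1138 contigs differed, 930 higher and 208 lower at 0.5 EC50. Median-of-ratios scaling gave 458 higher and 418 lower, quantile normalization 464 and 539, and an equal total 572 and 207. The total was 202 without the 4 libraries with other low-value steps and 639 with the batch term, and without 0.5 EC50 replicate 1, 2 or 3 or 0.2 EC50 replicate 1, 2 or 3 it was 707, 433, 382, 556, 545 and 740.

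Between 0.5 and 0.1 EC50, 3219 contigs differed, 2808 higher and 411 lower at 0.5 EC50. TRINITY_DN13892_c0_g1_i1_2 was higher by 3.86 ± 0.381 on the log2 scale (SE, adjusted p = 0.000288), and TRINITY_DN2512_c0_g2_i1_3 was lower by a log2 difference of -1.64 ± 0.242 (adjusted p = 0.00219). Median-of-ratios scaling turned the split, to 863 higher and 1107 lower, quantile normalization gave 808 and 806, and an equal total kept it at 2140 and 404. The median log2 difference of all contigs was 0.25 as deposited and 0.00234 after median-of-ratios scaling. The total was 44 without the 4 libraries with other low-value steps, with 1 library left at 0.1 EC50, and 747 with the batch term. Without 0.5 EC50 replicate 2 or 3 or 0.1 EC50 replicate 2 or 3 it was 1614, 1605, 1327 and 1552.

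No contig passed the threshold between 0.2 and 0.1 EC50 in limma's test, where 2315 had an unadjusted p under 0.05. Leaving out 0.1 EC50 replicate 1 gave 29 contigs and leaving out 0.5 EC50 replicate 1 gave 2. Library weights gave 48, and 0 were called both without the 4 libraries with other low-value steps and with the batch term.

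**Figure D3:**
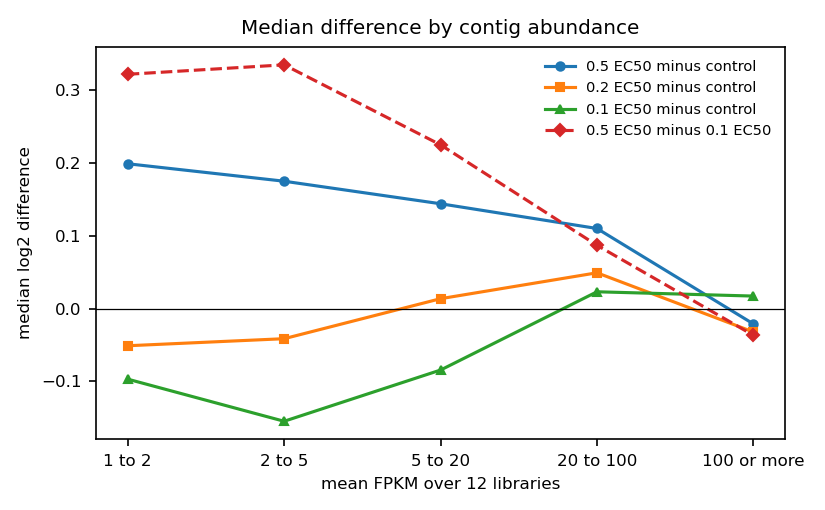
Median log2 difference of contigs by their mean FPKM over the 12 libraries, for each dose minus control and for 0.5 minus 0.1 EC50 (dashed), from values as deposited. For 0.5 minus 0.1 EC50 the median was 0.32 for contigs at 1 to 2 FPKM and -0.04 for contigs at 100 FPKM or more.

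Among the contigs called at any dose, 3289 in all, 192 were higher at all 3 doses and 146 were lower at all 3, and median-of-ratios scaling gave 92 and 190. TRINITY_DN11245_c0_g1_i1_1 and TRINITY_DN2075_c0_g1_i8_3 were among the contigs lower at all 3. At both 0.2 and 0.1 EC50, 321 contigs were higher and 631 lower, and 0 were called in opposite directions. Independent lists would share 25.1 and 55.6, and unchanged groups compared with the same controls shared 0 and 0 in 100 simulations. Almost nothing is called in unchanged groups, so neither value shows how much the shared controls add to the overlap of groups that do change. At both 0.5 and 0.2 EC50, 470 were higher and 183 lower (67.4 and 19.4 for independent lists), with 11 in opposite directions. At both 0.5 and 0.1 EC50, 206 were higher and 162 lower (31.3 and 28.8), with 32 in opposite directions. Of these 32, 28 were higher at 0.5 and lower at 0.1 EC50 and 4 the reverse, against 8 and 10 after median-of-ratios scaling.

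The log2 differences from control had a correlation across contigs of 0.674 between 0.2 and 0.1 EC50, of 0.552 between 0.5 and 0.2 EC50 and of 0.48 between 0.5 and 0.1 EC50. Simulated unchanged groups gave 0.499, 0.5 and 0.5, the value for groups of equal spread. The controls had lower mean correlations with their own group (0.9172 to 0.9366) than the dose libraries (0.945 to 0.9572). With noisier controls the value without change may lie above 0.5, so the simulated values are no exact reference. The covariances were 0.158, 0.148 and 0.129, above the simulated ones by 0.0934, 0.0836 and 0.0645. The share of contigs whose differences had the same sign was 71.8%, 67.2% and 58.4% in the same order, against 66.7% in the simulations. For 0.5 and 0.1 EC50 it lay below the simulated share. The median log2 difference of all contigs from control was 0.156 at 0.5 EC50 and -0.0853 at 0.1 EC50 as deposited. Such opposite shifts of all contigs can lower the share, so it does not show opposite responses at these doses. Contigs are not independent replicates, and with 3 controls that cannot be split into parts of 2 libraries, part of the excess may come from the shared controls. Without control replicate 3 the last 2 correlations were 0.653 and 0.621, without 0.2 EC50 replicate 1 the first 2 were 0.568 and 0.442, and without 0.1 EC50 replicate 1 the first was 0.562. The value without change is higher with 2 controls and lower with 2 libraries at a dose. These correlations are therefore not to be read against 0.5.

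A difference among the 4 groups was called for 3402 contigs, 20.3% of those tested, and a linear trend with the dose for 840, of which 655 increased and 185 decreased. Median-of-ratios scaling gave 269 increases and 413 decreases, quantile normalization 316 and 469, and an equal total 391 and 169. Without the 4 libraries with other low-value steps the totals were 510 and 190, and with the batch term 1287 and 327. The first total was 2048, 2235 and 2206 without 0.5 EC50 replicate 2, 0.5 EC50 replicate 3 and 0.1 EC50 replicate 2. The second was 311, 204, 331, 1305 and 424 without 0.5 EC50 replicate 1, 2 or 3, 0.2 EC50 replicate 2 and control replicate 2.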

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

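The tests of causes in this part, the counts of splits included, were written down after the results were seen, and the limits used in them were chosen then. Both results below were picked out because the response at 1 dose differed from that at another in a direct test. Between 0.5 and 0.1 EC50, 3219 contigs differed, and between 0.5 and 0.2 EC50, 1138.

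Splits of the libraries were counted for each comparison. The real grouping was the 1 split of 10 with as many calls in each of 5 comparisons, and 10 splits are too few for a share under 0.05. The real and highest other values were 1596 and 0 for 0.5 EC50 against control, 1742 and 62 for 0.2 EC50 against control, 1619 and 0 for 0.1 EC50 against control, 1138 and 1 for 0.5 against 0.2 EC50, and 3219 and 0 for 0.5 against 0.1 EC50. For 0.2 against 0.1 EC50 the real value was 0, which 10 of 10 splits reached. Over all 12 libraries, 1 of 100 splits called as many contigs for any difference among the groups (3402, highest other 960) and 1 of 100 for the linear trend (840, the highest other split at 14.6% of that count), so chance in how these libraries fell into groups can be excluded for these. Chance differences between cultures are not excluded by it, since nothing says that the libraries of a group are separate cultures. The low-value steps, which are spread unevenly over the groups, are not excluded by it either. With those steps as a batch term the totals were 1287 for any difference and 327 for the trend.

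Contigs of low abundance sat higher at 0.5 than at 0.1 EC50, with a median log2 difference of 0.33 for contigs under 5 FPKM (0.302 to 0.349 when each library was left out). Median-of-ratios scaling lowered it from 0.32 to 0.15 at 1 to 2 FPKM and from 0.335 to 0.10 at 2 to 5 FPKM, and moved contigs at 100 FPKM or more to -0.35. A few abundant contigs taking more of the total would move every class alike, and the tables argue against it, since contigs at 100 FPKM or more had a median of -0.03682 (-0.0668 to 0.0331). The libraries with other low-value steps remain open as a cause: the median was 0.3309 without them, with 1 library left at 0.1 EC50, and the 0.252 of a fit with a batch term fell to 0.0723 when that library, 0.1 EC50 replicate 1, was left out. A difference by the last number of the contig name, whose meaning is not known here, also remains open, with medians of 0.322, 0.1051, 0.389 and 0.387, and so does the dose itself, untested against these.

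In control replicate 2, 101 contigs held over 50% of their summed FPKM over the 12 libraries, against 13 in the next library, 0.1 EC50 replicate 2. Of these, 99 stayed under 5% of that level in every other library, made up 2.1% of the FPKM of control replicate 2, were called at no dose against control in limma's test, and all have names ending in 3, as do 5080 of the 16732 tested contigs. A label exchanged among the 12 libraries cannot be judged from these contigs. The summed FPKM of the 101 contigs in any other library was at most 0.3611% of that in control replicate 2. They had been chosen for holding over 50% of their FPKM there, which keeps the other libraries low whatever the labels are. RNA of another source may be the cause and stays open, since 9 of the 10 contigs at 100 FPKM or more lay under 0.5% of that level in every other library but had been chosen by those levels. A sample from outside the series also stays open, with a mean correlation with the other controls of 0.9172 (0.8994 and 0.9349) against 0.9135 with 0.2 EC50, and no biological explanation was tested.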

How the results depend on the processing

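The settings with other low-value steps and the shared calls of 3 scalings were chosen after seeing the data, all others before. No named contig changed direction in any setting. The contigs named for 0.5 EC50 and those that fell at 0.2 and 0.1 EC50 stayed called in all settings run on them. A call was lost in 16 of 24 settings for TRINITY_DN1915_c0_g4_i1_2, 7 of 23 for TRINITY_DN12187_c0_g1_i1_1, 5 of 24 for TRINITY_DN6226_c0_g4_i1_3 and 2 of 23 for TRINITY_DN16465_c0_g1_i1_4. The gene lists, with their estimated correlation, were not run. The depth is unknown, so what it limits cannot be given. A count was taken as moved at over 1.5 times, or where 0 became another number, and a correlation at 0.1. Except where fewer libraries or a stricter rule shows it, the cause was not tested.

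The counts that moved were as follows. With library weights they were 3693 for 0.5 EC50 against control, 2542 for 0.5 against 0.2 EC50, 5809 for 0.5 against 0.1 EC50, 48 for 0.2 against 0.1 EC50, 6370 for any difference and 3284 for the trend. A change of at least 2-fold left 455, 390 and 378 for 0.5, 0.2 and 0.1 EC50 against control, 303 and 796 for 0.5 against 0.2 and 0.1 EC50, 825 for any difference and 386 for the trend. Fits of the 2 groups compared gave 1010 and 691 for 0.5 and 0.1 EC50 against control and 310 for 0.5 against 0.2 EC50. For 0.5 against 0.1 EC50 a mean of at least 5 FPKM gave 1830, median-of-ratios scaling 1970 and quantile normalization 1614, and for 0.5 against 0.2 EC50 no filter gave 750. For 0.2 against 0.1 EC50, where 0 were called, a pseudocount of 0.1 gave 3, an equal total 4, quantile normalization 1 and no prior trend 1.

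Without the 4 libraries with other low-value steps the counts were 624, 488 and 152 for 0.5, 0.2 and 0.1 EC50 against control, 202 and 44 for 0.5 against 0.2 and 0.1 EC50, 510 for any difference and 190 for the trend. The steps as a batch term gave 750 and 510 for 0.5 and 0.1 EC50 against control, 639 and 747 for 0.5 against 0.2 and 0.1 EC50, 1287 for any difference and 327 for the trend. Calls shared by 3 scalings were 810 for 0.5 EC50 against control, 562 for 0.5 against 0.2 EC50 and 1038 for 0.5 against 0.1 EC50.

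As the range over all libraries, moved or not, leaving out each library gave 439 to 1886, 923 to 1968 and 812 to 1759 for 0.5, 0.2 and 0.1 EC50 against control. It gave 382 to 1227 for 0.5 against 0.2 EC50, 1327 to 3691 for 0.5 against 0.1 EC50 and 0 to 29 for 0.2 against 0.1 EC50. It gave 2048 to 3680 for any difference and 204 to 1305 for the trend. Correlations ranged from 0.4423 to 0.6533 for 0.5 and 0.2 EC50, 0.3799 to 0.6213 for 0.5 and 0.1 EC50 and 0.5624 to 0.7523 for 0.2 and 0.1 EC50. The correlation expected without change also shifts when a control or a dose library is left out, and these ranges include that shift.

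Pairing by replicate number was not shown: 8 of 18 pairs with the same number had a correlation of deviations over 0.1 (-0.247 to 0.293). As a hint from the data, the mean was 0.0531 for the same number and -0.0266 for other numbers, and 8 of 12 libraries correlated best with their own number. The replicate number as a block moved 1 count, that for 0.2 against 0.1 EC50, and gave 2342, 2302 and 2135 for 0.5, 0.2 and 0.1 EC50 against control, 1513, 4036 and 1 for 0.5 against 0.2, 0.5 against 0.1 and 0.2 against 0.1 EC50, 4380 for any difference and 956 for the trend. It also ended the call of TRINITY_DN1915_c0_g4_i1_2 at 0.1 EC50 (log2 difference 2.02) and of no other named contig.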
